A study of Mus musculus with 18 samples.

How the data were processed

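RNA was measured by polyA mRNA sequencing in mouse embryonic stem cells differentiated toward cardiomyocytes. The cells were the GLI1-FTA line in the A2Lox.cre background, which was given doxycycline (dox) to induce GLI1, a transcription factor of the Hedgehog pathway. Per the labels' protocols, GLI1 overexpression (OE) samples received 500 ng/ml dox for 24 hours from D5 to D6 and were then washed. Control samples are labelled untreated, so no sample received dox without the induced gene. The libraries were made with a TruSeq kit and sequenced as stranded single-end reads of 50 bases, per the labels. The 18 libraries fall into 7 groups by day and condition, with sizes given below. Nothing in the labels says whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

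The authors deposited a table of raw read counts per gene symbol for all 18 libraries, and the tests rest on these whole-number counts as deposited. The aligner, the counting program, its use of strand and the genome build behind the counts are not given in the sources used here. Genes with near-identical copies, overlapping genes and antisense genes are uncertain for that reason. The authors also deposited TPM values for the 4 D5 controls, which entered no test because the same libraries have counts. The authors' deposited tables give log2 fold changes at D6, D8 and D12, and the column names of the D6 table are those DESeq2 writes. The deposited p-values and adjusted p-values in those tables were used only beside the values computed here. The count columns carry the day, the condition and a library number but no replicate number, so libraries are named below by day, condition and that number.

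Counts were analysed in R 4.3.3 with edgeR 4.0.16. Of the 23337 genes in the table, 14892 passed the expression filter with a minimum count of 10. Library sizes were scaled by trimmed mean of M-values (TMM), and a robust quasi-likelihood model with 1 coefficient per group was fitted to all 18 libraries, so that the 7 groups shared 1 estimate of the spread per gene. Quasi-likelihood F tests gave p-values, which were adjusted by Benjamini-Hochberg within each contrast and called under 0.05. Effects of GLI1 OE were compared between days by testing the interaction contrast itself. Counts scaled by edgeR to library size (CPM) are given as mean ± SD over the libraries of a group, and log2 fold changes of GLI1 OE comparisons with their standard error (SE).

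Before the data were examined, 18 gene lists were fixed from general knowledge: Hedgehog target genes and pathway components, pluripotency, primitive streak, second heart field, core cardiac transcription factors, sarcomere, cardiac calcium handling, cardiac energy metabolism, 6 lists of other cell types, cell cycle, developmental timing and the integrated stress response. They hold 320 different symbols, and 3 of these (Foxf1, Map2 and Spi1) stand in the table under the older names Foxf1a, Mtap2 and Sfpi1, found through the RefSeq gene table of assembly GRCm38.p6. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 18 lists. Camera with an estimated correlation, fry for a change in 1 direction and fry for changes in either direction were alternatives, the last left out of the ranges given because it tests no direction.

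Genes were named by a rule fixed at the same time. Gli1 came first, followed for each GLI1 OE comparison by the 6 genes with the largest rise and the 6 with the largest fall among genes that passed the test, had a mean log2 CPM of at least 1 and had groups that did not overlap. Predicted gene names were left out. Up to 3 members of each list with the smallest adjusted p were added. The control comparisons took 4 genes per direction and 2 per list. A list without a member past the threshold was represented by its member of highest expression. Where a group held 0 counts for a named gene, the fold is given as a lower bound against a floor of 3 counts over the group. Where it held 1 to 3 counts, the ratio is given with an exact 95% interval. These bounds and intervals cover counting error only. Results for some genes chosen by this rule are not reported here.

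The GLI1 OE effect at each day was also set against the change with time in controls, as a correlation of log2 fold changes across genes. The time axis took controls of other days than the effect: D8 over D5 for the effects at D6 and D12, and D12 over D5 for the effect at D8. Genes are not independent replicates, so these correlations carry no p-value. The 200 genes with the smallest p rising along each axis, and the 200 falling, were tested as sets with camera.

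The model was tested on data simulated from the means, spread and sizes of these libraries, with 200 genes changed, over the 14602 that passed the filter. At D6 edgeR recovered 60.3% of genes changed 2-fold, 89.4% at 4-fold and 93.9% at 8-fold, with 9 false calls. D8 gave 52.9%, 83.3% and 92.4% with 5, and D12 48.5%, 81.8% and 93.9% with 4. DESeq2 made 35, 40 and 31 false calls by day. D8 recovery may be lower, as its GLI1 OE pair varied most.

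Whether adjacent library numbers mark paired samples was checked by correlating deviations from the group means across genes. At D6 the pairs 3 with 4, 11 with 12 and 15 with 16 gave correlations of 0.52, 0.62 and 0.45, so the D6 libraries meet the rule for pairs set beforehand. Values come from the model without the block, with the blocked value beside them where it changed a D6 call or moved a count by over 1.5 times. This pairing comes from the library numbers in the column names and the data, not from the labels. At D8 the pairs gave 0.49 and at D12 the pairs gave -0.23. The blocked fit took the 14 libraries of D6, D8 and D12 with the pair within each day as a block.

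Alternatives planned beforehand were DESeq2 1.42.0, limma-voom, size factors computed as in DESeq2, no low-count filter, a stricter filter of at least 1 CPM, fits to the compared groups alone, an absolute log2 change of at least 1, an adjusted p under 0.10, other time axes and leaving out each library in turn. Alternatives chosen after seeing the data were the blocks by adjacent library numbers, a fit without D5, the edgeR exact test, time axes without D5 and a restriction to genes with little shared sequence. For the last, the percentage of each gene's 50-base transcript windows that also occur in transcripts of another gene was computed from GENCODE M21 transcripts and was available for 90.5% of the 14892 tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.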

Results

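The experiment asked how a pulse of GLI1, the transcription factor that carries the Hedgehog signal into the nucleus, changes mouse cardiac progenitors while it is expressed and after it is withdrawn. PolyA RNA was sequenced from 18 libraries. Untreated controls were collected at D5 (n = 4), D6 (n = 3), D8 (n = 2) and D12 (n = 2). GLI1 overexpression (OE) cells, given doxycycline from D5 to D6 and then washed, were collected at D6 (n = 3), D8 (n = 2) and D12 (n = 2).

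Total counts per library were 24842624 to 26184339 at D5, 20187924 to 22608134 at D6, 20524374 to 22064021 at D8 and 18470785 to 22301324 at D12, the lowest being D12 GLI1 OE library 10. Each library detected 15889 to 16567 genes. The first principal component held 52.8% of the variance and placed the days in order, from -98.3 to -64.8 at D5 to 108 to 118 at D12. The second held 14.1% and separated the D6 GLI1 OE libraries (43.4 to 64.2) from the D6 controls (0.666 to 19.5). D5 control libraries 1 and 2 differed by a chi-square of 7.17 per gene, against 53.5 to 99.2 for the other D5 pairs, and were kept as 2 samples. The largest difference within a group was that between D8 GLI1 OE libraries 14 and 18, with a chi-square of 129 per gene.

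The D6 comparison asked which genes respond while GLI1 is induced. Gli1 itself rose from 14 ± 7.28 CPM in the 3 controls to 909 ± 134 CPM in the 3 GLI1 OE libraries (log2 fold change 6.02 ± 0.59, edgeR adjusted p = 4.31e-05, higher in 3 of 3). Whether reads from the induced copy map to Gli1 is not stated in the labels. At D8 it was 1.19 ± 0.373 CPM in GLI1 OE and 0.964 ± 0.3 CPM in controls (log2 fold change 0.30 ± 0.89, edgeR adjusted p = 0.976), and at D12 0.956 ± 0.228 and 0.855 ± 0.066 CPM (0.18 ± 0.98, edgeR adjusted p = 0.997).

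**Figure D1:**
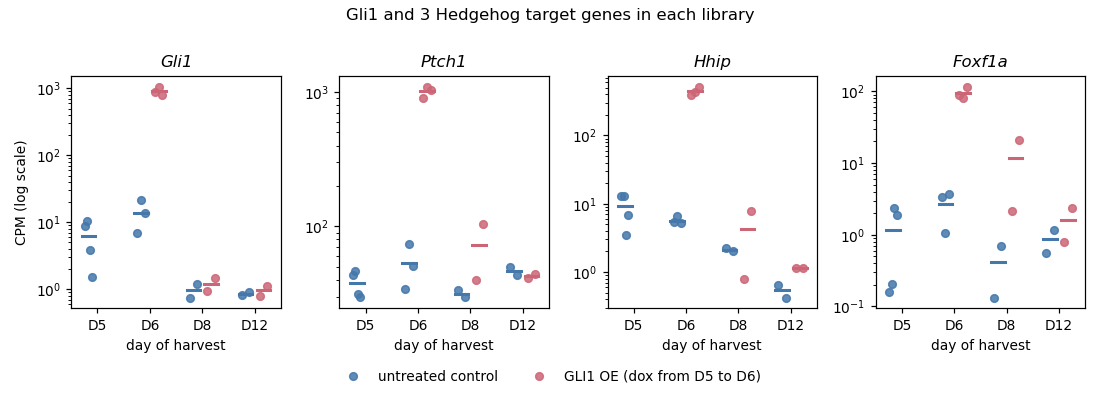
CPM on a logarithmic axis of Gli1, Ptch1, Hhip and Foxf1a in each of the 18 libraries (points) with the group mean (bar), by day and condition; Hhip and Foxf1a were chosen after their values were seen. At D6 Gli1 averaged 909 CPM with GLI1 OE and 14 CPM in controls, and Ptch1 1010 and 53.2 CPM, whereas at D12 Ptch1 averaged 43 and 46.6 CPM.

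Hedgehog target genes rose at D6. Of the 19 measured, 12 rose in the edgeR test, and 17 passed when adjusted over the list alone. Ptch1, which encodes the Hedgehog receptor, rose from 53.2 ± 19.7 to 1010 ± 98.2 CPM (log2 fold change 4.25 ± 0.35, edgeR adjusted p = 1.53e-05). The forkhead factor gene Foxl1 rose by 6.51 ± 0.50 log2 units (edgeR adjusted p = 6.7e-06). Foxa2, a forkhead factor of floor plate and endoderm, rose from 0.567 ± 0.278 to 97.6 ± 13.3 CPM (7.43 ± 0.97, edgeR adjusted p = 0.00042). The cyclin genes Ccnd1 and Ccnd2 and the proto-oncogene Mycn were members that did not pass. The list median was 3.91 and the list was higher (camera adjusted p = 3e-21). This held at adjusted p = 0.029 with an estimated correlation, and the 10 alternatives ranged from 6.6e-23 to 0.029. With the pairing of D6 libraries in the model, 14 of the 19 rose.

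Hedgehog pathway components did not rise as a list. Of 11 measured, 2 fell, and 2 passed when adjusted over the list alone. Gli3, the GLI protein that mainly acts as a repressor, fell by 0.60 ± 0.11 log2 units (edgeR adjusted p = 0.00717). Gas1, a Hedgehog co-receptor gene, fell by 1.25 ± 0.25 (edgeR adjusted p = 0.0103), a call lost without D6 GLI1 OE library 16 (0.0602). The list median was -0.35 and the camera adjusted p was 0.057, which became 0.036 without D6 control library 3.

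The genes with the largest rises at D6 were nearly silent in controls. Pnliprp1, a pancreatic lipase-related gene, had 550 counts with GLI1 OE and 0 in controls, a rise of at least 182-fold (edgeR adjusted p = 0.00154). Epha8, an ephrin receptor gene, rose by 9.14 ± 0.52 log2 units (edgeR adjusted p = 3.29e-07). Ciita, the activator of MHC class II genes, went from 2 to 854 counts, a ratio of 424 with an exact 95% interval of 117 to 3510 (edgeR adjusted p = 0.000124). The potassium channel subunit gene Kcns2 went from 1 to 454 counts (ratio 451, interval 80.5 to 17900, edgeR adjusted p = 0.000124). The aldehyde dehydrogenase gene Aldh3b2 went from 3 to 887 counts (ratio 294, interval 100 to 1430, edgeR adjusted p = 0.00014).

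Among the genes with the largest falls at D6, Irx4, a ventricular transcription factor gene, fell by 5.20 ± 0.98 log2 units (edgeR adjusted p = 0.00681). Tbx2, a T-box repressor of chamber genes, fell by 3.62 ± 0.47 (edgeR adjusted p = 0.000412). Hcn4, the pacemaker channel gene, fell by 2.95 ± 0.39 (edgeR adjusted p = 0.000447). Kcnj5, a subunit gene of the acetylcholine-gated potassium channel, fell by 3.10 ± 0.77 (edgeR adjusted p = 0.0344). Irf5, an interferon regulatory factor gene, fell by 3.70 ± 0.69 (edgeR adjusted p = 0.00663), and Ltk, a receptor tyrosine kinase gene, fell by 2.96 ± 0.65 (edgeR adjusted p = 0.0171). The Kcnj5 call was lost in 5 of 6 fits without 1 library, all except that without GLI1 OE library 12, with adjusted p up to 0.171. The Ltk call was lost without D6 control library 15, GLI1 OE library 12 or GLI1 OE library 16, with adjusted p up to 0.0933.

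The cardiac lists were lower at D6 by the camera test, while few of their members passed alone. Of 15 core cardiac transcription factors, 1 fell (Irx4; 2 with the pairing of D6 libraries) and 3 passed when adjusted over the list alone. All 15 estimates were below 0, with a median of -0.98 (camera adjusted p = 0.00014; adjusted p = 0.7 with an estimated correlation, range over 10 alternatives 2.7e-05 to 0.7). Of 27 sarcomere genes 0 passed in edgeR or limma-voom, 6 had an unadjusted p under 0.05 and DESeq2 called 1, while 2 fell with the pairing. Tpm1, which encodes a tropomyosin, did not pass (log2 fold change -0.51 ± 0.31, edgeR adjusted p = 0.48). The sarcomere median was -1.29, with 26 of 27 estimates below 0 (camera adjusted p = 2.1e-05; adjusted p = 0.7 with an estimated correlation, range 4.2e-08 to 0.7).

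Genes of cardiac calcium handling and conduction moved in both directions at D6. Of 20 measured, 3 fell (5 with the pairing) and 1 rose, and 7 passed when adjusted over the list alone. Hcn4 and Kcnj5 fell as given above, and Kcnh2, which encodes a repolarising potassium channel, fell by 1.51 ± 0.33 (edgeR adjusted p = 0.0181). Casq2, the calcium-binding protein gene of the sarcoplasmic reticulum, rose by 4.34 ± 0.72 (edgeR adjusted p = 0.00283). The list median was -1.37 (camera adjusted p = 0.0035; adjusted p = 0.7 with an estimated correlation, range 0.00088 to 0.7). The Kcnh2 call was lost without D6 control library 15 or GLI1 OE library 4, 12 or 16, with adjusted p up to 0.0881.

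Of 18 cardiac energy metabolism genes 0 passed at D6 in edgeR or limma-voom, 4 had an unadjusted p under 0.05 and DESeq2 called 1, while 1 rose and 1 fell with the pairing. Hadha, a gene of fatty acid oxidation, did not pass (log2 fold change 0.01 ± 0.15, edgeR adjusted p = 0.986). The median was -0.99, or -0.93 with members without counts at their bound (camera adjusted p = 0.014; adjusted p = 0.79 with an estimated correlation, range 0.0031 to 0.79). The list call was lost without D6 control library 11 (0.066), control library 15 (0.078), GLI1 OE library 4 (0.056) or GLI1 OE library 16 (0.063).

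Progenitor and neural genes changed singly at D6. Among 19 second heart field genes 2 rose (2 rose and 2 fell with the pairing) and 2 passed when adjusted over the list alone. Osr1, a mesoderm transcription factor gene that is also in the Hedgehog target list, rose by 3.10 ± 0.69 log2 units (edgeR adjusted p = 0.0185). Six2, a homeobox gene of progenitor cells, rose by 3.41 ± 0.83 (edgeR adjusted p = 0.0314). The second heart field list had a median of -0.17, a mean of 0.17 and a camera direction of lower (adjusted p = 0.92). Of 15 neural genes 1 rose and 3 fell, and 5 passed when adjusted over the list alone (median -0.10, camera adjusted p = 0.2). Sox11, a transcription factor gene of neural and mesenchymal progenitors, rose by 1.24 ± 0.23 (edgeR adjusted p = 0.00567). Dcx, a microtubule gene of young neurons, fell by 3.03 ± 0.57 at low counts, 6 against 51 (edgeR adjusted p = 0.00627). Irx3, an Iroquois homeobox gene, fell by 1.23 ± 0.30 (edgeR adjusted p = 0.0283). Six2 and Irx3 lost their call whichever of the 6 libraries was left out, with adjusted p of 0.0653 to 0.125 and 0.0629 to 0.113. Osr1 lost its call without D6 control library 3 or 15 or GLI1 OE library 12 or 16, with adjusted p up to 0.0994.

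Each of 4 lists of other cell types had 1 member that rose at D6. With the pairing 2 paraxial genes rose and 1 fell, 3 endothelial genes rose and 1 fell, and 1 smooth muscle gene rose and 1 fell. Sox9, a chondrogenic and sclerotome factor gene, rose by 1.60 ± 0.29 log2 units (edgeR adjusted p = 0.00548), the other 9 paraxial genes did not pass, and 3 passed when adjusted over the list alone. The paraxial list had a median of -0.59 (-0.15 with members without counts at their bound), a mean of 0.07 and a camera direction of higher (adjusted p = 0.9). Sox18, an endothelial factor gene, rose by 2.42 ± 0.59 (edgeR adjusted p = 0.0324), among 15 endothelial genes of which 3 passed when adjusted over the list alone. The endothelial median was 0.31 (camera adjusted p = 0.16), and that list was higher with the D6 pairing (0.012) or without control library 3 (0.016) or GLI1 OE library 12 (0.02). Fbln1, a matrix gene, rose by 0.81 ± 0.19 (edgeR adjusted p = 0.0251) among 17 genes of smooth muscle and mesenchyme, 1 passing when adjusted over the list alone (median -0.61, camera adjusted p = 0.59). Alb, the albumin gene, went from 1 to 64 counts (ratio 63.6, exact 95% interval 11 to 2550, edgeR adjusted p = 0.0171) among 15 endoderm genes, 1 passing when adjusted over the list alone. The endoderm median was 0.43 (camera adjusted p = 0.15, 0.042 with the pairing). Sox18 lost its call whichever library was left out (0.0517 to 0.131). Fbln1 lost it without control library 3 or 11 or GLI1 OE library 4 or 16 (up to 0.127), and Alb in all fits but that without GLI1 OE library 12 (up to 0.0833).

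In the other 6 lists 0 genes passed in edgeR at D6 without the pairing. With it 2 pluripotency genes fell, 2 primitive streak genes rose and 1 fell, 1 blood gene rose and 4 fell, 1 stress response gene rose, and 0 cell cycle genes and timing factors passed. The counts at an unadjusted p under 0.05 and by DESeq2 were 2 and 2 for 8 pluripotency genes, of which 2 passed when adjusted over the list alone, and 1 and 0 for 12 primitive streak genes. They were 1 and 0 for 13 blood genes, 0 and 0 for 22 cell cycle genes, 0 and 0 for 11 developmental timing factors, and 1 and 1 for 20 genes of the integrated stress response. Limma-voom called 0 in each. Medians and camera adjusted p were -0.18 and 0.31, -1.17 and 0.31, -0.52 and 0.61, 0.05 and 0.77, 0.11 and 0.39, and 0.08 and 0.78, in the same order. Tdgf1, a Nodal co-receptor gene, was lower by an estimate of -1.48 ± 0.43 log2 units (edgeR adjusted p = 0.0744, 0.0445 with the pairing). Kdr, the VEGF receptor gene, had an estimate of 0.40 ± 0.37 (0.706, 0.0441 with the pairing), and the embryonic globin gene Hbb-bh1 one of -0.87 ± 1.32 (0.852, 0.042 with the pairing). The proliferation gene Top2a (0.13 ± 0.22, edgeR adjusted p = 0.867), the let-7-regulated chromatin gene Hmga2 (0.23 ± 0.22, 0.702) and the serine synthesis gene Psat1 (0.14 ± 0.28, 0.902) did not pass.

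**Figure D2:**
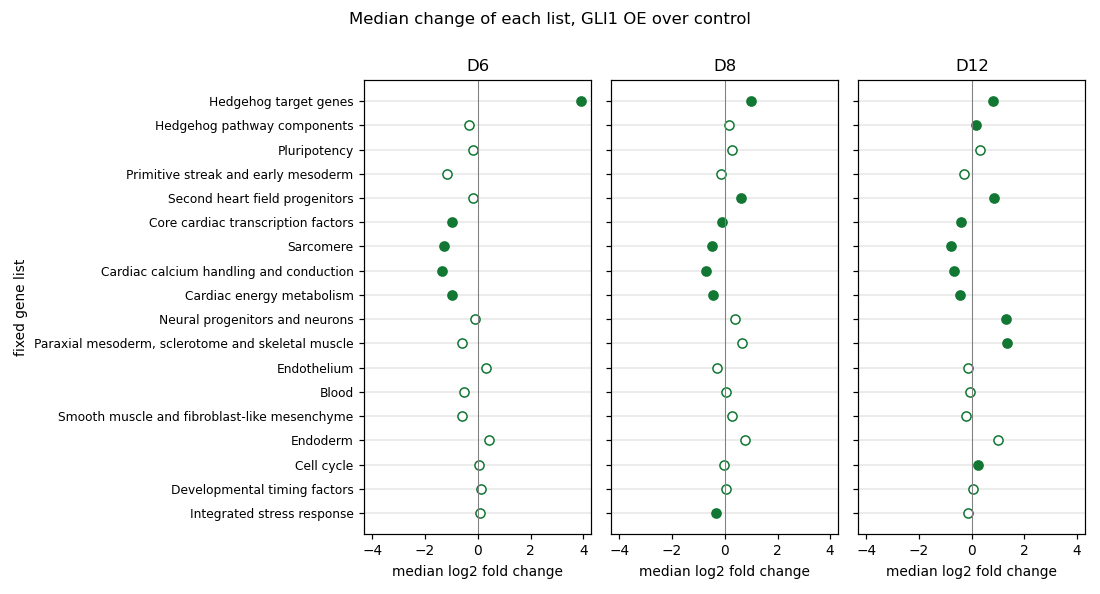
Median log2 fold change, GLI1 OE over control, of each of 18 gene lists (1 point per list) at D6, D8 and D12; filled points have a camera adjusted p under 0.05. Hedgehog target genes stand highest at D6 with 3.91, and calcium handling and conduction lowest with -1.37.

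In total 616 of 14892 genes passed at D6, 449 higher and 167 lower (72.9% higher), and 2348 had an unadjusted p under 0.05. Blocking adjacent numbers at D6, D8 and D12 gave 1358 (736 higher, 622 lower), holding 571 of the 616, and 2239 with the D12 pairs crossed. The 616 fell to 370 without D6 control library 3, 365 without control library 15 and 330 without GLI1 OE library 16. The authors' deposited table calls 1946 (1051 higher, 895 lower), including 610 of the 616, and log2 fold changes correlate over 14561 shared genes (r = 0.999). No control received doxycycline, so the drug and GLI1 cannot be told apart.

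The D8 comparison asked what remained after GLI1 was withdrawn. In edgeR 0 of 14892 genes passed, with 886 at an unadjusted p under 0.05 and a smallest adjusted p of 0.489. DESeq2 called 40 (24 higher, 16 lower), the edgeR exact test 6 and limma-voom 0. Without D8 GLI1 OE library 14 edgeR called 49, and without D8 control library 13 it called 1. Ptch1 was 72.2 ± 46 CPM with GLI1 OE and 31.5 ± 2.75 CPM in controls (log2 fold change 1.20 ± 0.39, edgeR adjusted p = 0.698). Its value was 105 CPM in library 18 and 39.7 CPM in library 14. Foxa2 had 209 counts, 204 of them in library 18, against 4 (5.67 ± 1.42, edgeR adjusted p = 0.489), and Foxl1 an estimate of 1.24 ± 0.51 (0.799).

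The Hedgehog target list was higher at D8, with 15 of 19 estimates above 0 and a median of 1.00 (camera adjusted p = 0.0016; adjusted p = 0.73 with an estimated correlation, range over 8 alternatives 9.7e-08 to 0.8). In edgeR 0 members passed over all genes, 7 when adjusted over the list alone and 8 had an unadjusted p under 0.05, while DESeq2 called 2 and limma-voom 0. Without D8 GLI1 OE library 18 the list was not called (0.71). Its median was 1.70 for library 18 over control library 17 and 0.03 for library 14 over control library 13. Its member of highest expression, Ccnd2, did not pass (log2 fold change 0.33 ± 0.34, edgeR adjusted p = 0.928). The second heart field list was also higher, with a median of 0.62 and 14 of 19 estimates above 0 (camera adjusted p = 0.0058; adjusted p = 0.73 with an estimated correlation, range 0.002 to 0.8). It was not called without control library 17 (0.063) or GLI1 OE library 18 (0.36). In it 0 members passed, 6 had an unadjusted p under 0.05 and DESeq2 called 0. Meis2, a homeobox gene of that field, had an estimate of 0.60 ± 0.39 (edgeR adjusted p = 0.883).

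The cardiac lists were lower at D8 with 0 members passing in edgeR, DESeq2 or limma-voom. Those at an unadjusted p under 0.05 numbered 0 of 15 core transcription factors, 1 of 27 sarcomere genes, 2 of 20 calcium handling genes and 1 of 18 energy metabolism genes. Medians were -0.50 for sarcomere (25 of 27 estimates below 0, camera adjusted p = 4e-05, range 8.2e-12 to 0.8) and -0.73 for calcium handling (17 of 20 below 0, 2.4e-05, range 9.7e-08 to 0.8). They were -0.43 for energy metabolism (7e-04, range 1.8e-09 to 0.8) and -0.10 for core transcription factors (0.036, range 5e-07 to 0.8). For each of these 4 lists adjusted p = 0.73 with an estimated correlation. Myh6, the atrial myosin gene (log2 fold change -0.72 ± 1.12, edgeR adjusted p = 0.955), Tbx20, a cardiac T-box gene (-0.17 ± 0.70, 0.986), the sodium-calcium exchanger gene Slc8a1 (-0.65 ± 1.06, 0.957) and the muscle enolase gene Eno3 (-0.06 ± 0.58, 0.997) did not pass.

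These D8 calls changed without single libraries. Without GLI1 OE library 18 the camera adjusted p was 0.31 for sarcomere, 0.31 for calcium handling, 0.31 for energy metabolism and 0.08 for core transcription factors. Without control library 13 it was 0.068 for sarcomere, 0.37 for energy metabolism and 0.27 for core transcription factors, the last also being lost without control library 17 (0.055). Library 18 over control library 17 gave a sarcomere median of -2.21, and library 14 over control library 13 gave -0.04.

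The integrated stress response list was lower at D8, with all 20 estimates below 0 and a median of -0.32 (camera adjusted p = 0.0019; adjusted p = 0.73 with an estimated correlation, range 4.2e-05 to 0.8). In it 0 genes passed in edgeR or DESeq2, and 1 had an unadjusted p under 0.05. The mTOR inhibitor gene Ddit4 had an estimate of -0.28 ± 0.48 (edgeR adjusted p = 0.957). That call was lost without control library 17 (0.071) or GLI1 OE library 14 (0.14).

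The remaining 11 lists were not called at D8, and 0 of their genes passed in edgeR or DESeq2. Medians and camera adjusted p were 0.16 (0.05 with members without counts at their bound) and 0.38 for pathway components, 0.28 and 0.71 for pluripotency, -0.13 and 0.69 for primitive streak, 0.39 and 0.56 for neural genes, and 0.06 and 0.69 for timing factors. They were 0.67 and 0.31 for paraxial genes, of which 2 passed when adjusted over the list alone, and 0.75 (0.30 at the bound) and 0.38 for endoderm. Endothelium had -0.30 and 0.23, and was lower without control library 13 (0.045) or GLI1 OE library 18 (0.0041). Signs differed in 3 lists: blood had a median of 0.06, a mean of -0.29 and a camera direction of lower (adjusted p = 0.64), smooth muscle a median of 0.27 and a direction of lower (0.77), and cell cycle a median of -0.03, a mean of 0.01 and a direction of higher (0.97). The cell cycle list was higher without GLI1 OE library 14 (0.021) and lower without library 18 (0.0041). Those at an unadjusted p under 0.05 numbered 3 neural and 2 paraxial genes, 0 cell cycle genes and timing factors, and 1 in each other list. Sox11 (0.69 ± 0.27, edgeR adjusted p = 0.799), the apolipoprotein gene Apoe (-0.94 ± 0.53, 0.859), the Hedgehog transducer gene Smo (0.21 ± 0.20, 0.919) and the endothelial factor gene Ets1 (-0.30 ± 0.35, 0.939) did not pass. Nor did Tdgf1 (0.14 ± 0.51, 0.983), Kdr (0.02 ± 0.45, 0.998), Foxc1 (-0.20 ± 0.22, 0.933), Lmo2 (0.46 ± 0.66, 0.955), Col3a1 (0.21 ± 1.10, 0.991), Top2a (-0.08 ± 0.27, 0.98) or Hmga2 (0.16 ± 0.26, 0.957).

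The D12 comparison asked whether any difference lasted 6 days after the pulse. In edgeR 0 of 14892 genes passed, with 840 at an unadjusted p under 0.05 and a smallest adjusted p of 0.326. DESeq2 called 14, all higher, the edgeR exact test 56 and limma-voom 1, and edgeR called 5 without D12 GLI1 OE library 10. Six2 had 352 counts with GLI1 OE and 2 in controls (edgeR adjusted p = 0.492). Irx3 (log2 fold change 1.54 ± 0.37, edgeR adjusted p = 0.492) and Tbx2 (1.68 ± 0.51, 0.618) did not pass.

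At D12 the lists with the highest medians were paraxial and neural. The paraxial list had a median of 1.33 with 9 of 10 estimates above 0 (camera adjusted p = 8.9e-06; adjusted p = 0.088 with an estimated correlation, range over 8 alternatives 1.1e-06 to 0.088). In it 0 genes passed over all genes, 1 when adjusted over the list alone and 5 had an unadjusted p under 0.05, while DESeq2 called 0 and limma-voom 1. The neural list had a median of 1.29 with 13 of 15 above 0 (camera adjusted p = 0.00011; adjusted p = 0.15 with an estimated correlation, range 6.7e-05 to 0.15). In it 0 passed over all genes, 4 when adjusted over the list alone and 5 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Both lists were called whichever library was left out. Sox11 (0.88 ± 0.28, edgeR adjusted p = 0.644) and the forkhead gene Foxc1 (0.29 ± 0.22, 0.956) did not pass.

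Hedgehog and progenitor lists were higher at D12 with 0 members passing in edgeR. Hedgehog targets had a median of 0.82 with 16 of 19 above 0 (camera adjusted p = 0.00086; adjusted p = 0.61 with an estimated correlation, range 0.00086 to 0.61). Pathway components had a median of 0.16 with 11 of 11 above 0 (camera adjusted p = 0.03; adjusted p = 0.61 with an estimated correlation, range 0.0073 to 0.87). The second heart field list had a median of 0.83, and 2 members passed when adjusted over the list alone (camera adjusted p = 0.0015; adjusted p = 0.44 with an estimated correlation, range 0.0016 to 0.44). The cell cycle list had a median of 0.23 with 22 of 22 above 0 (camera adjusted p = 0.00065; adjusted p = 0.65 with an estimated correlation, range 3.8e-07 to 0.66). Those at an unadjusted p under 0.05 numbered 4, 1, 4 and 1, and DESeq2 called 2 second heart field genes and 0 in the others. Ccnd2 (0.35 ± 0.34, edgeR adjusted p = 0.971), the co-receptor gene Cdon (0.01 ± 0.38, 1), Meis2 (-0.01 ± 0.39, 1) and Top2a (0.23 ± 0.27, 0.973) did not pass. Without D12 control library 19 or GLI1 OE library 20 the adjusted p was 0.11 or 0.13 for Hedgehog targets, 0.8 or 0.87 for pathway components, 0.11 or 0.12 for second heart field and 0.66 or 0.11 for cell cycle.

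The cardiac lists were lower at D12, again with 0 members passing in edgeR, DESeq2 or limma-voom. The unadjusted p was under 0.05 for 1 energy metabolism gene and for 0 genes of the other 3 lists. All 27 sarcomere estimates were below 0, with a median of -0.77 (camera adjusted p = 0.0012, range 7.4e-06 to 0.72), and energy metabolism had a median of -0.44 (0.0055, range 0.00055 to 0.72). For both, adjusted p = 0.68 with an estimated correlation. All 20 calcium handling estimates were below 0, with a median of -0.67 (camera adjusted p = 0.00086, range 5.8e-05 to 0.61), as were 14 of 15 core transcription factors, with -0.39 (0.0055, range 0.0021 to 0.65). For both, adjusted p = 0.61 with an estimated correlation. Myh6 (log2 fold change -0.94 ± 1.13, edgeR adjusted p = 0.973), the calcium pump gene Atp2a2 (-0.77 ± 0.39, 0.895), the cardiac factor gene Gata6 (-0.46 ± 0.40, 0.971) and the myoglobin gene Mb (-0.93 ± 0.97, 0.971) did not pass. Without control library 19 or GLI1 OE library 20 the adjusted p was 0.54 or 0.28 for sarcomere, 0.17 or 0.12 for calcium handling, 0.11 or 0.28 for core transcription factors and 0.38 or 0.32 for energy metabolism.

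The other 8 lists were not called at D12. Medians and camera adjusted p were 0.33 and 0.51 for pluripotency, -0.14 and 0.39 for endothelium, -0.05 and 0.29 for blood, -0.21 and 0.36 for smooth muscle, 0.06 and 0.57 for timing factors and -0.15 and 0.15 for the stress response. Primitive streak had a median of -0.29 (-0.11 at the bound), a mean of 0.06 and a camera direction of higher (adjusted p = 0.74). Endoderm had a median of 0.98 (0.39 at the bound) and 0.19, and was higher without GLI1 OE library 10 (0.0029). In these lists 0 genes passed in edgeR, DESeq2 or limma-voom, and only smooth muscle and endoderm had 1 gene each with an unadjusted p under 0.05. Pdgfra, a receptor gene of early mesoderm (-0.43 ± 0.87, edgeR adjusted p = 0.984), the stress response factor gene Atf4 (-0.33 ± 0.25, 0.954) and Apoe (-0.68 ± 0.52, 0.959) did not pass. Nor did Klf4 (0.06 ± 0.33, 0.997), Eng (-0.01 ± 0.51, 1), Lmo2 (0.38 ± 0.67, 0.979), Col3a1 (-0.38 ± 1.10, 0.993) or Igf2bp2 (-0.03 ± 0.11, 0.994).

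Whether the GLI1 OE effect differed between days was tested directly by interaction. Between D8 and D6 it differed for 94 genes (10 higher, 84 lower), and between D12 and D6 for 90 (14 higher, 76 lower). The effect on Ptch1 was lower at D8 than at D6 by an estimate of -3.05 ± 0.50 log2 units (edgeR adjusted p = 0.0112) and at D12 by -4.36 ± 0.51 (0.00194). Foxl1 changed by -5.27 ± 0.70 (edgeR adjusted p = 0.00352) and -5.11 ± 0.88 (0.0129), Epha8 by -9.48 ± 1.11 (0.00169) and -8.23 ± 1.59 (0.03), and Casq2 by -6.06 ± 1.14 (0.0277) and -5.38 ± 1.03 (0.03). Tbx2, which fell at D6, had a higher effect at D8 by 4.77 ± 0.70 (edgeR adjusted p = 0.00584) and at D12 by 5.30 ± 0.70 (0.00385). Irx3 differed at D12 (2.77 ± 0.47, edgeR adjusted p = 0.0129). Gli1 itself differed by -5.72 ± 1.08 (edgeR adjusted p = 0.0277) and -5.84 ± 1.18 (0.0415). For Hcn4 (2.31 ± 0.58, edgeR adjusted p = 0.121) and Irx4 (3.35 ± 1.34, 0.551) no difference between D8 and D6 passed. Between D12 and D8 0 genes differed in edgeR, DESeq2 or limma-voom, with 355 at an unadjusted p under 0.05.

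These interaction counts depended on single libraries and on pairing. With the block by adjacent library numbers they were 216 (54 higher, 162 lower) and 204 (61 higher, 143 lower). The count between D8 and D6 was 48 without D8 control library 13, 51 without D8 control library 17, 57 without D6 control library 3 and 60 without D6 control library 15. That between D12 and D6 was 12 without D12 GLI1 OE library 20, 45 without D12 control library 9, 49 without D12 control library 19, 54 without D12 GLI1 OE library 10 and 59 without D6 GLI1 OE library 16.

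Genes called at D6 were followed as sets. The 449 higher genes had a median of 2.09 at D6, 0.15 at D8 (65.3% with the same sign) and 0.05 at D12 (55.9%). The 167 lower genes had medians of -1.10, -0.22 (75.4%) and -0.14 (70.7%). At D8 the camera adjusted p was 1.8e-05 for the higher set (adjusted p = 0.053 with an estimated correlation) and 1.8e-10 for the lower set (adjusted p = 0.05 with an estimated correlation). At D12 it was 0.02 and 0.0011 (adjusted p = 0.27 with an estimated correlation for each).

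**Figure D3:**
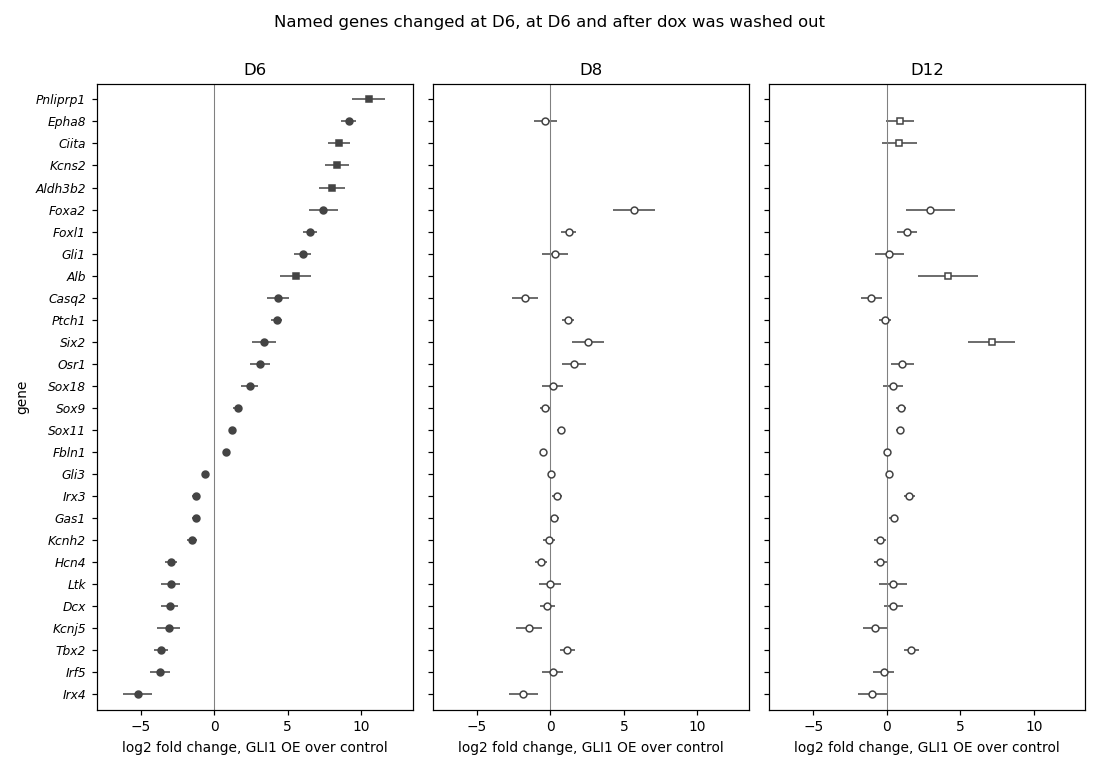
Log2 fold change, GLI1 OE over control, ± SE at D6, D8 and D12 for named genes that changed at D6; filled symbols have an edgeR adjusted p under 0.05, squares mark a group with 3 or fewer counts, and values with 3 or fewer counts in both groups are not drawn. Ptch1 goes from 4.25 at D6 to 1.20 at D8 and -0.11 at D12, and Tbx2 from -3.62 to 1.15 and 1.68.

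Whether GLI1 OE moved cells along or against normal time was asked by setting its effect against the change in controls of other days. At D6 the rank correlation across genes with D8 over D5 was -0.11 (r = -0.07), and the 200 genes rising most clearly along that axis were not called (camera adjusted p = 0.74), nor were the 200 falling (0.14). Along D12 over D5 the falling genes were higher (camera adjusted p = 0.037; adjusted p = 0.92 with an estimated correlation). At D8 the rank correlation with D12 over D5 was -0.22 (r = -0.18). Of the 200 rising genes 140 were lower at D8, with a median of -0.09 (camera adjusted p = 6.9e-05; adjusted p = 0.35 with an estimated correlation), and the 200 falling genes were not called (0.063). Along the planned axis of D6 over D5 both sets were lower, 0.023 for the rising and 0.036 for the falling genes (adjusted p = 0.42 for each with an estimated correlation). Along D12 over D6, chosen after seeing the data, both sets were called, the rising genes lower (3.5e-07) and the falling genes higher (1.4e-08; adjusted p = 0.17 and 0.21 with an estimated correlation). At D8 the rank correlation became -0.035 without GLI1 OE library 18. At D12 it was -0.08, and the sets were not called (0.16 for each). D5 libraries form a numbering series of their own, so batch and day cannot be told apart in any axis that uses them.

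The control comparison of D6 with D5 asked how untreated cells change over the day of the pulse, and all libraries named from here on are controls. Gja5, an atrial and arterial connexin gene, rose by 5.97 log2 units (edgeR adjusted p = 0.000569; 4.21 without D6 library 3), Hcn4 by 2.41 (0.000216) and Irx4 by 2.42 (0.0354). Of 20 calcium handling genes 6 rose, 6 adjusted over the list alone (median 0.83, camera adjusted p = 0.018; adjusted p = 0.9 with an estimated correlation, range over 10 alternatives 0.0048 to 0.9). Of 15 core transcription factors 1 rose, 0 adjusted over the list alone (median 0.43, camera adjusted p = 0.11), and that list was higher without D5 library 4 (0.021). Of 27 sarcomere genes 0 passed in edgeR, 5 had an unadjusted p under 0.05, DESeq2 called 4 and limma-voom 1. The sarcomere median was 1.00 with 25 estimates above 0 (camera adjusted p = 0.004; adjusted p = 0.9 with an estimated correlation, range 0.00016 to 0.9). Tpm1 did not pass (-0.03, edgeR adjusted p = 0.955). The sarcomere and calcium calls were lost without D5 library 3 (0.054 and 0.074) or D6 library 11 (0.075 and 0.075). The Irx4 call was lost without D5 library 1, 2 or 3 or D6 library 3 or 15 (up to 0.164).

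The endothelial list had the highest median between D5 and D6. Of 15 endothelial genes 9 rose, 12 adjusted over the list alone (median 1.65, camera adjusted p = 0.00011; adjusted p = 0.9 with an estimated correlation, range 1.8e-07 to 0.9). Eng, a TGF-beta co-receptor gene, rose by 1.83 (edgeR adjusted p = 0.00573) and Sox18 by 2.56 (edgeR adjusted p = 0.006). The embryonic globin gene Hbb-y rose by 4.27 (edgeR adjusted p = 0.0088; 7.27 without D5 library 3), as 1 of 13 blood genes, with 1 adjusted over the list alone (median 1.44, or 0.87 at the bound, camera adjusted p = 0.0046; adjusted p = 0.9 with an estimated correlation, range 3.8e-05 to 0.9). The red cell anion exchanger gene Slc4a1 rose by 5.32 (edgeR adjusted p = 0.00171). The microRNA gene Mir5109 had 307 counts at D6 and 0 at D5, at least 150-fold (edgeR adjusted p = 1.99e-07).

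Other lists held single changes between D5 and D6. Of 19 Hedgehog targets 1 rose in edgeR. The metabolic receptor gene Esrra rose by 0.67 (edgeR adjusted p = 0.00341) as 1 of 18 energy genes, and Sox17, an endoderm and endothelial factor gene, by 2.16 (0.00541) as 1 of 15 endoderm genes. Each of these 3 lists had 1 adjusted over the list alone, with medians and camera adjusted p of 0.14 and 0.32, 0.43 and 0.19, and 0.01 and 0.77. Tcf15, a somite factor gene, rose by 2.24 (edgeR adjusted p = 0.00664), with 3 of 10 paraxial genes adjusted over the list alone, a median of -0.16 and a camera direction of higher (0.89). Fbln1 rose by 0.65 (edgeR adjusted p = 0.0199), as 1 of 17 smooth muscle genes over all genes and over the list alone (median 0.37, camera adjusted p = 0.2), a call lost without D5 library 1 or 2 or D6 library 15 (up to 0.117). The replication clamp gene Pcna fell by 1.41 (edgeR adjusted p = 2.43e-05) and the mitotic cyclin gene Ccnb1 fell by 1.21 (0.00127), while 1 of 22 cell cycle genes rose, 3 adjusted over the list alone (median 0.22, camera adjusted p = 0.61). The serine synthesis gene Phgdh fell by 2.08 (edgeR adjusted p = 0.000807), as 1 of 20 stress response genes over all genes and over the list alone (median -0.11, camera adjusted p = 0.54).

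In 6 further lists 0 genes passed in edgeR between D5 and D6. Medians, camera adjusted p and counts at an unadjusted p under 0.05 were -0.13, 0.77 and 3 for pathway components, 0.39, 0.22 and 1 for primitive streak, and -0.52, 0.28 and 6 for second heart field. They were -0.24, 0.61 and 5 for neural genes and -0.16, 0.77 and 2 for timing factors. Pluripotency had 1 such gene, a median of -0.01 and a camera direction of higher (adjusted p = 0.9). DESeq2 called 2 pathway components, 2 second heart field genes and 1 in each of the other 4 lists, and limma-voom 0. Smo (0.03, edgeR adjusted p = 0.914), Tdgf1 (-0.10, 0.902), Sox11 (-0.04, 0.921), Meis2 (-0.50, 0.286) and Hmga2 (-0.34, 0.28) did not pass. Kdr had an estimate of 0.90 (edgeR adjusted p = 0.0908), and passed without D5 library 3 (0.0453) or D6 library 11 (0.0334). The primitive streak list was higher without D5 library 3 (0.047).

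The largest falls between D5 and D6 were all in ribosomal protein genes. Rps29 fell by 11.34 log2 units, from 444 ± 68.8 to 0.164 ± 0.0629 CPM (edgeR adjusted p = 2.99e-10). Rps3a fell by 9.13 (edgeR adjusted p = 3.74e-12) and Rpl36a fell by 9.01 (4.95e-12). Of 73 ribosomal protein genes 69 fell, with a median of -3.29. Those with at least 20% of their 50-base windows shared with another gene had a median of -4.82 (37 genes), and those with under 5% shared -0.20 (5 genes).

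**Figure D4:**
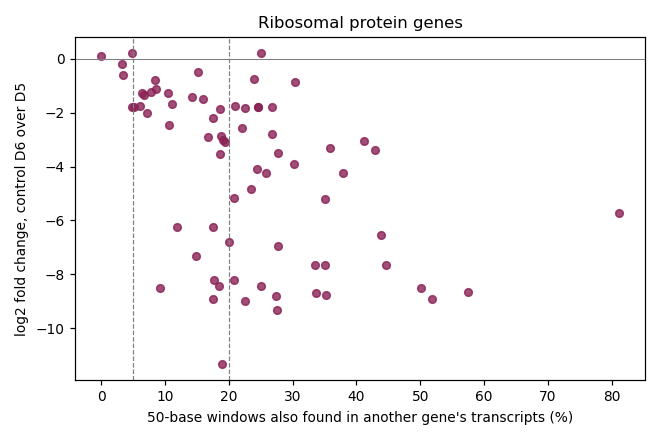
Log2 fold change of control D6 over D5 (vertical) of each ribosomal protein gene (1 point per gene) against the percentage of its 50-base windows that also occur in another gene (horizontal); dashed lines mark 5% and 20%. The 37 genes at or above 20% have a median of -4.82 and the 5 genes under 5% a median of -0.20.

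In total 2738 genes changed between D5 and D6 in controls, 1250 higher and 1488 lower, and 1785 (1060 higher, 725 lower) among genes with under 5% shared windows. The count was 1561 without D6 library 15 and 1789 without D6 library 3. A batch of the D5 libraries cannot be separated from the day.

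The control comparison of D8 with D6 asked how cells change over the 2 days after the pulse. The energy metabolism list was higher: of 18 genes 6 rose, 7 adjusted over the list alone, with all 18 estimates above 0 and a median of 1.48 (camera adjusted p = 0.0046; adjusted p = 0.76 with an estimated correlation, range over 8 alternatives 0.00046 to 0.76). Mb rose by 6.41 log2 units (edgeR adjusted p = 0.000894; 4.01 without D8 library 13), and Pdk4, a brake on pyruvate oxidation, by 2.79 (0.00223). The energy call was lost without D8 library 13 (0.067). The potassium channel gene Kcnq1 rose by 2.06 (edgeR adjusted p = 0.0099), among 5 of 20 calcium handling genes that rose, 3 adjusted over the list alone (median 0.95, camera adjusted p = 0.15, 0.023 without D8 library 17). Mef2a, a myogenic factor gene, rose by 0.85 (edgeR adjusted p = 0.00264) and the cardiac homeodomain gene Hopx by 2.47 (0.00881), 2 of 15 core factors over all genes and over the list alone (median 0.30, camera adjusted p = 0.52). The Z-disc gene Myoz2 rose by 2.94 (edgeR adjusted p = 0.0322) and Tpm1 fell by 1.27 (0.0141), as 2 of 27 sarcomere genes rose, 1 fell and 0 passed adjusted over the list alone (median 0.52, camera adjusted p = 0.37). Without D8 library 13 the calls on Kcnq1 (0.154), Mef2a (0.0516), Hopx (0.202) and Tpm1 were lost. Tpm1 was also lost without D8 library 17 (up to 0.102), and Myoz2 whichever library was left out (0.0518 to 0.103).

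The cell cycle and stress response lists were lower between D6 and D8. Of 22 cell cycle genes 10 fell, 12 adjusted over the list alone (median -0.57, camera adjusted p = 0.0026; adjusted p = 0.76 with an estimated correlation, range 0.00064 to 0.76). The S-phase cyclin genes Ccne2 and Ccne1 had log2 fold changes of -1.03 (edgeR adjusted p = 0.000295) and -1.30 (0.000819). Lin28a, an RNA-binding protein gene of developmental timing, fell by 2.89 (edgeR adjusted p = 0.000481) and Lin28b fell by 0.95 (0.0047). Of 11 timing factors 4 fell and 1 rose, 5 adjusted over the list alone (median -0.27, camera adjusted p = 0.15). Of 20 stress response genes 11 fell and 3 rose, 16 adjusted over the list alone (median -1.05, camera adjusted p = 0.034; adjusted p = 0.76 with an estimated correlation, range 0.0046 to 0.76). The folate enzyme gene Mthfd2 fell by 2.91 (edgeR adjusted p = 9.69e-06) and the asparagine synthetase gene Asns fell by 1.72 (0.000424). The stress response call was lost without D6 library 3 (0.12) or D8 library 13 (0.054).

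Of 12 primitive streak genes 5 fell and 2 rose between D6 and D8, 8 adjusted over the list alone (median -2.44, camera adjusted p = 0.21). Fgf8, a growth factor gene of the streak, fell by 4.51 (edgeR adjusted p = 0.00199) and the homeobox gene Mixl1 fell by 5.65 (0.00742), lost without D8 library 13 or 17 (up to 0.0675). Of 8 pluripotency genes 2 fell and 1 rose, 5 adjusted over the list alone (median -0.27, camera adjusted p = 0.52), and among them the factor gene Tfcp2l1 fell by 1.94 (edgeR adjusted p = 0.0186) and the nuclear receptor gene Esrrb rose by 2.38 (0.0209). Both calls were lost without D8 library 13, that on Tfcp2l1 also without D8 library 17 (up to 0.122) and that on Esrrb without D6 library 3 or 15 (up to 0.486). Of 15 endoderm genes 4 fell and 1 rose, 5 adjusted over the list alone (median -1.87, or -0.19 at the bound, camera adjusted p = 0.21), and the epithelial keratin genes Krt18 and Krt8 fell, with log2 fold changes of -2.08 (edgeR adjusted p = 0.000752) and -2.06 (0.000754). Runx1, a blood factor gene, fell by 2.17 (edgeR adjusted p = 0.00841), as 1 of 13 blood genes over all genes and over the list alone (median -1, camera adjusted p = 0.23), lost without D8 library 13 (0.0789).

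The Hedgehog lists were not called between D6 and D8. Of 19 targets 4 fell, 4 adjusted over the list alone (median -0.76, camera adjusted p = 0.15). Mycn fell by 1.46 (edgeR adjusted p = 0.00028) and the homeobox gene Nkx2-9 fell by 2.98 (0.00331), lost without D8 library 13 (0.0505). Of 11 components 4 fell and 1 rose, 5 adjusted over the list alone (median -0.34, camera adjusted p = 0.23). The ligand gene Shh went from 79 counts to 0, at least 18.1-fold lower (edgeR adjusted p = 0.00536), and the co-receptor gene Boc rose by 2.01 (0.000603). Of 19 second heart field genes 2 rose and 2 fell, 3 adjusted over the list alone (median -0.14, camera adjusted p = 0.52), and of these the forkhead gene Foxc1 rose by 1.51 (edgeR adjusted p = 0.000121).

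The remaining 4 lists were not called between D6 and D8. Of 17 smooth muscle genes 4 rose and 2 fell, 8 adjusted over the list alone (median 1.06, camera adjusted p = 0.37). The actin-binding gene Tagln fell by 2.61 (edgeR adjusted p = 0.00144) and Fbln1 rose by 1.07 (0.00168). Of 15 endothelial genes 2 rose, over all genes and over the list alone, Ets1 by 1.50 (edgeR adjusted p = 0.00282) and Eng by 1.81 (0.00871), with a median of 0.29 (camera adjusted p = 0.37). Of 15 neural genes 2 rose, over all genes and over the list alone, Lhx2 by 1.87 (edgeR adjusted p = 0.000783) and Sox11 by 0.84 (0.018), the latter lost without D6 library 15 or D8 library 13 or 17 (up to 0.0871). The neural median was -0.31 with a camera direction of higher (adjusted p = 0.61). Of 10 paraxial genes 3 rose, over all genes and over the list alone, among them the somite gene Meox1 by 2.50 (edgeR adjusted p = 0.00795), lost without D8 library 13 (0.0531). The paraxial median was 1.03, or 0.33 at the bound (camera adjusted p = 0.21).

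Among the largest single changes between D6 and D8, Fgf23, a hormone gene, went from 1 to 254 counts (ratio 370, exact 95% interval 65.9 to 14700, edgeR adjusted p = 0.000908). Igfbp7, an insulin-like growth factor binding protein gene, rose by 5.73 (edgeR adjusted p = 0.000283), and the neuronal leucine-rich repeat gene Lrrn3 by 5.75 (0.000866). Vgf, a neuropeptide precursor gene, went from 331 to 3 counts (75.7-fold lower, interval 25.7 to 369, edgeR adjusted p = 0.0214). Trim67, a ubiquitin ligase gene, fell by 5.22 (edgeR adjusted p = 0.00559), and the ligand gene Wnt6 fell by 5.12 (0.000834). Vgf was lost without D6 library 3 or D8 library 13 or 17 (up to 0.125), and Trim67 without D8 library 13 or 17 (up to 0.0533). In total 5178 genes changed, 2573 higher and 2605 lower, and 2761 without D8 library 13.

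The control comparison of D12 with D8 asked how the cells change late in differentiation. Cell cycle genes fell: 21 of 22, all 22 adjusted over the list alone, with a median of -1.25 (camera adjusted p = 7e-09; adjusted p = 0.7 with an estimated correlation, range over 7 alternatives 1.3e-11 to 0.7). Ccne2 fell by 2.72 (edgeR adjusted p = 3.06e-06) and the replication helicase gene Mcm2 fell by 1.46 (1.99e-05). Of 11 timing factors 9 fell, over all genes and over the list alone (median -1.37, camera adjusted p = 4.5e-05; adjusted p = 0.7 with an estimated correlation, range 4.7e-06 to 0.7). Lin28a fell by 4.98 (edgeR adjusted p = 4.5e-05), and Arid3a, a let-7-repressed gene, fell by 1.37 (7.12e-05). Of 15 neural genes 7 fell and 1 rose, 9 adjusted over the list alone (median -1.47, camera adjusted p = 0.065). Lhx2 fell by 2.87 (edgeR adjusted p = 0.000126), while Stmn2, a neuronal microtubule gene, rose by 5.12 (0.000247).

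The smooth muscle and mesenchyme list was higher between D8 and D12. Of its 17 genes 3 rose, 1 adjusted over the list alone, with 16 estimates above 0 and a median of 1.82 (camera adjusted p = 0.031; adjusted p = 0.7 with an estimated correlation, range 0.013 to 0.7). The collagen gene Col5a2 rose by 1.98 (edgeR adjusted p = 0.00343), and the matrix gene Lum by 2.72 (0.032). The list call was lost without D8 library 13 (0.14) or D12 library 19 (0.063), and that on Lum without D8 library 13 or D12 library 9 or 19 (up to 0.176). Of 20 stress response genes 8 rose and 2 fell, 10 adjusted over the list alone (median 0.81, camera adjusted p = 0.062, 0.02 without D8 library 17). Ddit3, a gene of the stress-induced factor CHOP, rose by 2.91 (edgeR adjusted p = 0.000406) and Atf4 by 1.46 (0.000616). Among the largest rises were those of Ogn, a matrix proteoglycan gene (7, edgeR adjusted p = 0.00106), Kcne4, a channel subunit gene (6.63, 0.000114), and the stress gene Nupr1 (5.78, 0.014). Nupr1 was lost without D8 library 13 or 17 (up to 0.0974).

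Cardiac lists did not move together between D8 and D12. Of 27 sarcomere genes 0 passed in edgeR, DESeq2 or limma-voom or at an unadjusted p under 0.05 (median -0.27, camera adjusted p = 0.8), including Myh6 (0.23, edgeR adjusted p = 0.89). Of 20 calcium handling genes 2 rose and 1 fell, 3 adjusted over the list alone (median 0.43, camera adjusted p = 0.29). Casq2 rose by 4.78 (edgeR adjusted p = 0.000837) and Hcn4 fell by 1.69 (0.0103). Of 18 energy genes 2 rose, over all genes and over the list alone (median 0.04, camera adjusted p = 0.61), Esrra by 0.74 (edgeR adjusted p = 0.00531) and Pdk4 by 2.03 (0.02). Mef2a rose by 1.00 (edgeR adjusted p = 0.00163), as 1 of 15 core factors over all genes and over the list alone (median -0.64, camera adjusted p = 0.77). Of 19 second heart field genes 3 fell and 0 passed adjusted over the list alone (median -0.86, camera adjusted p = 0.61), and the progenitor factor gene Isl1 fell by 1.36 (edgeR adjusted p = 0.0297) and Hoxa2 fell by 2.04 (0.0362). Isl1 and Hoxa2 lost their calls whichever library was left out (0.0678 to 0.17 and 0.0641 to 0.167). Hcn4 lost it without D8 library 17 or D12 library 9 (up to 0.0825), Esrra without D8 library 17 (0.0689), and Pdk4 without D8 library 17 or D12 library 19 (up to 0.155).

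The pluripotency, primitive streak and blood lists were not called between D8 and D12. Tdgf1 fell by 5.85 (edgeR adjusted p = 5.03e-05) and the Krüppel-like factor gene Klf2 fell by 3.12 (0.00244), as 2 of 8 pluripotency genes fell and 1 rose, 3 adjusted over the list alone (median -0.85, camera adjusted p = 0.77). Lhx1 went from 32 counts to 1 (27.2-fold lower, exact 95% interval 4.54 to 1110, edgeR adjusted p = 0.0353), as 1 of 12 primitive streak genes fell and 0 passed adjusted over the list alone (median -0.67, camera adjusted p = 0.63). Hbb-y fell by 6.60 (edgeR adjusted p = 0.0103), as 1 of 13 blood genes over all genes and over the list alone (median -1.51, camera adjusted p = 0.61). Among the largest falls, Dpysl4, a cytoskeletal gene, went from 196 to 3 counts (55.4-fold lower, interval 18.7 to 271, edgeR adjusted p = 0.000209), and Cyp26a1, a retinoic acid-degrading enzyme gene, fell by 5.12 (0.0339). Lhx1 and Cyp26a1 lost their calls without D8 library 17 or D12 library 9 or 19 (up to 0.357 and 0.4), and Hbb-y without D12 library 9 or 19 (up to 0.0827).

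Hedgehog, paraxial, endoderm and vascular lists were not called between D8 and D12. Of 19 Hedgehog targets 4 fell and 1 rose, 4 adjusted over the list alone (median -0.43, or -0.25 at the bound, camera adjusted p = 0.49), and Mycn fell by 2.05 (edgeR adjusted p = 4.83e-05) and Hsd11b2, a steroid dehydrogenase gene, fell by 4.07 (6.18e-05). Of 11 components 3 fell and 1 rose, 4 adjusted over the list alone, with a median of -0.17, a mean of 0.18 and a camera direction of lower (adjusted p = 0.77). Gas1 rose by 2.11 (edgeR adjusted p = 0.000226) and the ciliary receptor gene Gpr161 fell by 1.42 (0.00162). Sox9 fell by 2.27 (edgeR adjusted p = 0.000452) and Foxc1 fell by 0.64 (0.0367), so that 2 of 10 paraxial genes fell, 1 adjusted over the list alone (median -0.65, or -0.54 at the bound, camera adjusted p = 0.61). Of 15 endoderm genes 2 fell and 1 rose, 1 adjusted over the list alone, with a median of 0, a mean of 0.23 and a camera direction of lower (0.89). Krt8 fell by 1.79 (edgeR adjusted p = 0.0025) and the keratin gene Krt19 fell by 1.52 (0.0315). Of 15 endothelial genes 0 passed in edgeR, DESeq2 or limma-voom or at an unadjusted p under 0.05 (median 0.37, camera adjusted p = 0.63), Eng having an estimate of 0.96 (edgeR adjusted p = 0.162). Foxc1 lost its call whichever library was left out (0.0545 to 0.221), and Krt19 without D8 library 13 or D12 library 9 or 19 (up to 0.195).

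**Figure D5:**
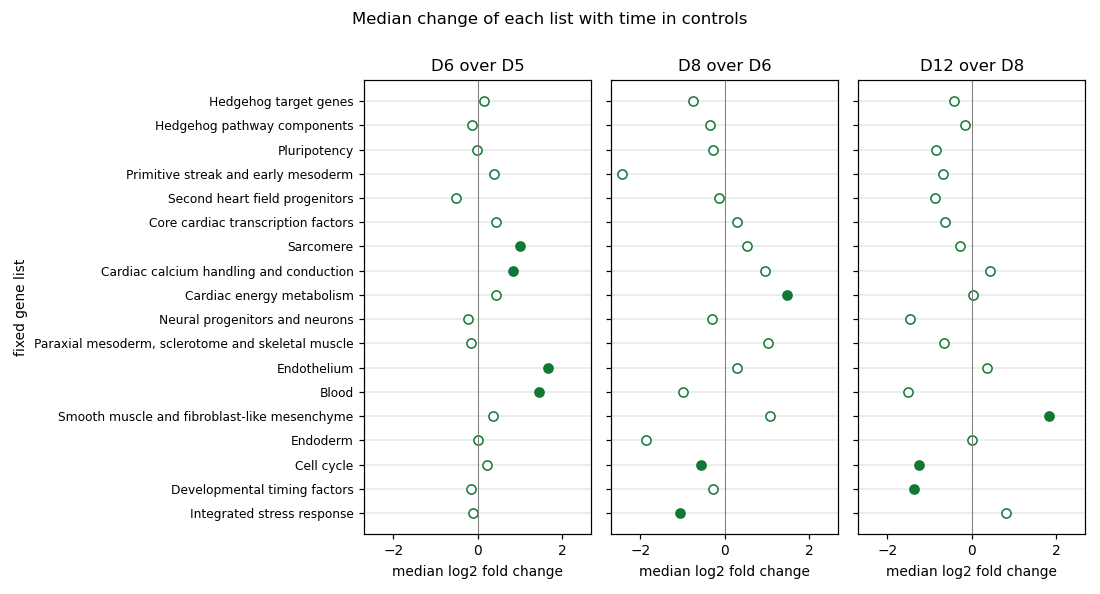
Median log2 fold change between control days of each of 18 gene lists (1 point per list) for D6 over D5, D8 over D6 and D12 over D8; filled points have a camera adjusted p under 0.05. Cell cycle lies at -0.57 for D8 over D6 and -1.25 for D12 over D8, and smooth muscle and mesenchyme at 1.82 for D12 over D8.

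In total 5411 genes changed between D8 and D12, 2521 higher and 2890 lower. The count was 3492 without D8 library 17 and 3599 without D12 library 19.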

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

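The tests of shared reads among ribosomal protein genes, of a stress response to doxycycline, of a lower share of cardiac cells and of left-over Gli1 transcripts were chosen after the result was seen. In D5 control library 3, 3 genes lay far from the other D5 libraries. Hbb-y was 3.32 CPM against 0.0798 to 0.127, Sox18 was 6.88 CPM against 1.01 to 1.98, and Meis2 was 65.1 CPM against 144 to 161. These are 3 of 27 gene groups tested, and chance gives about 5% of groups. No cause was tested for library 3.

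The effect of GLI1 OE differed between days for 94 genes at D8 against D6 and for 90 at D12 against D6, by an edgeR test of the difference. Among named genes the log2 effect at D8 minus that at D6 was -9.48 for Epha8, -6.06 for Casq2, -5.72 for Gli1, -5.27 for Foxl1, -3.05 for Ptch1 and 4.77 for Tbx2. For D12 minus D6 it was -8.23 for Epha8, -5.84 for Gli1, -5.38 for Casq2, -5.11 for Foxl1, -4.36 for Ptch1, 2.77 for Irx3 and 5.30 for Tbx2. Doxycycline was present only until D6, so the withdrawal of GLI1 and of the drug are not separated.

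Other splits of the libraries were counted for both comparisons with at least 3 libraries per group. At D6 the real split called 616 genes and the highest of the 9 others 0, including the 3 others that part all 3 pairs, and 10 splits are too few for a share under 0.05. Of 35 splits of the D5 and D6 controls, 1 called as many genes as the real split (2738), and the highest other called 448. D5 libraries 1 and 2, nearly alike, counted as 2, so neither chance nor a D5 batch is excluded.

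Ribosomal protein genes fell between D5 and D6 in controls. A fall of their expression as the whole cause is argued against by the 5 genes with under 5% shared windows, whose median log2 change was -0.20 with a standard error of 0.45. Among ribosomal protein genes the median with at least 20% shared windows lay lower than that with under 5% by -4.62, so reads shared with copies, counted at D5 and not later, are a candidate explanation. Over all tested genes the same difference was -0.55, between the bounds of 0.5 and 1 set beforehand, so that a general change in the handling of shared reads stays open. Batch and day cannot be told apart, because all D5 libraries belong to 1 series.

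The cardiac lists were lower under GLI1 OE at D6. An integrated stress response to doxycycline is argued against by that list's median of 0.08 with a standard error of 0.1. Only an even shift was tested, in which a lower share of cardiac cells would raise the lists of other cell types alike. Their medians spread by 1.04 with a standard error of 0.6, from smooth muscle to endoderm, which decides neither way, so such a shift may contribute and an effect of GLI1 on these genes also stays open. Untreated controls leave other effects of the drug untested.

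At D8 the Hedgehog target genes were higher in GLI1 OE library 18 than in library 14. For the 12 targets raised at D6, library 18 over 14 had a median log2 ratio of 1.76, and control library 17 over 13 had -0.08. A difference already present in the controls is argued against, as their ratio was -0.047 of that in the GLI1 OE libraries. Gli1 in library 18 was 1.23 times that in control library 17, which argues against left-over transcripts counted as Gli1. It excludes neither those of the induced copy, if its reads do not map to Gli1, nor GLI1 protein, which was not measured. A later withdrawal or a difference in differentiation of that culture could remain, and 2 libraries do not separate them.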

How the results depend on the processing

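The alternatives chosen after seeing the data are named above. Where a value moved, the cause was not tested, except that a stricter threshold or fewer genes lower a count by construction. The planned block by replicate number was not run, as the count columns carry none, nor was a paired analysis of the control days possible. Size factors computed as in DESeq2, both filters and the fit without D5 moved no total by over 1.5 times, and limma-voom moved only that of D12. Without D5 the genes lower at D6 rose from 167 to 272 and the interaction genes higher from 10 to 22 (D8) and 14 to 25 (D12).

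With DESeq2 the genes changed numbered 1030 at D6, 40 at D8 and 14 at D12, the interactions 233 (D8 against D6) and 281 (D12 against D6), and D6 calls recurred 18 times, 15 at D8 and 3 at D12 with Nkx2-3 in both, whereas edgeR called 0 genes at either day. Limma-voom called 1 gene at D12. Fitting only the groups compared gave 1254 genes at D6 and 208 for the interaction of D12 with D6. An absolute log2 change of at least 1 left 702 genes for D6 over D5, 2058 for D8 over D6 and 2438 for D12 over D8. An adjusted p under 0.10 gave 151 and 141 genes for the interactions at D8 and D12.

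The block by adjacent library numbers gave 1358 genes at D6, and 216 and 204 for the interactions, and changed no other total by over 1.5 times. At D6 it raised the Hedgehog targets that rose from 12 to 14, gained the endothelial and endoderm lists and Tdgf1, Kdr and Hbb-bh1, and changed no other call on a list or a named gene at D6. It lost the core transcription factor list and gained endothelium at D8, and lost pathway components and gained the stress response at D12. On D6 libraries alone it gave 4576. Crossing the D12 pairs gave 3 genes at D12, 59 at D8 and 2239 at D6. The exact test gave 1846, 6 and 56 genes at D6, D8 and D12. Genes with under 5% shared windows gave 1785 for D6 over D5.

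Of 18 lists, camera called 5 at D6, 7 at D8, 10 at D12 and 4, 3 and 3 for D6 over D5, D8 over D6 and D12 over D8. With an estimated correlation it called 1, 0, 0, 0, 0 and 0, in the same order. Fry for 1 direction called 1, 0, 1, 1, 0 and 5. Fry for either direction called 0 at D8, 2 at D12, 14 for D8 over D6 and 12 for D12 over D8. The rank correlation with control time was -0.027 at D6 along D12 over D8, -0.091 at D8 along D6 over D5 and -0.045 at D12 along D6 over D5.

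Leaving out 1 library at a time gave these lowest and highest counts: D6 330 to 458, D8 0 to 49, D12 0 to 5, D6 over D5 1561 to 2736, D8 over D6 2761 to 4358, D12 over D8 3492 to 3900, and the interactions 48 to 91 (D8 against D6) and 12 to 76 (D12 against D6). The lists called ranged from 4 to 7 at D6, 3 to 7 at D8, 2 to 11 at D12, 2 to 5 for D6 over D5, 1 to 4 for D8 over D6 and 2 to 4 for D12 over D8. The rank correlations ranged from -0.177 to -0.039 at D6, -0.268 to -0.035 at D8 and -0.083 to -0.033 at D12. With 1 of 2 libraries left out, the other is assumed to vary like the remaining groups.

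Over all alternatives the named genes gave 2190 values on the same side of the threshold, 136 that lost a call and 14 that gained one. No called gene changed direction, while estimates of genes that did not pass changed sign, such as Tdgf1 at D8 (-1.26 to 0.84) and Myh6 at D8 (-3.8 to 0.19). With 18470785 to 26184339 counts per library, genes with a few counts, such as Dcx and Alb, are limited by depth.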

Other observations

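The genes in this part were chosen after their values were seen. On simulated data with changed genes DESeq2 made 40 false calls at D8 and 31 at D12. True changes are unknown here, so those numbers do not give the share of its 40 and 14 calls that may be false. Of its calls 15 at D8 and 3 at D12 had passed at D6 in the same direction. Independent calls would share 1.08 higher and 0.387 lower genes at D8 and 0.63 higher genes at D12. At D8 the 8 higher genes, most so in library 18, were Colec10, Fgfr2, Foxa2, Foxf2, Gpr20, Hapln3, Nkx2-3 and Tmem158. The 7 lower genes were Alcam, Gfod1, Kcnh7, Med12l, Negr1, Popdc3 and Rpp25. Foxf2, a Hedgehog-responsive gene, was 0.509 and 20.1 CPM in D8 GLI1 OE libraries 14 and 18 and 0.0442 and 0.0872 CPM in the controls (DESeq2 adjusted p = 0.00381, edgeR 0.489).

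Nkx2-3, a homeobox gene of pharyngeal and gut mesoderm, was higher in GLI1 OE at all 3 days by DESeq2. It was 2.4, 2.47 and 5.92 CPM at D6, 3.56 and 25.7 CPM at D8 and 0.511 and 11.2 CPM at D12, and at most 0.133 CPM in the 11 controls (DESeq2 adjusted p = 5.57e-05, 0.00116 and 0.0309, edgeR 0.489 at D8 and 0.492 at D12). Six2 at D12 was 1.42 and 14.6 CPM against 0 and 0.106 CPM (DESeq2 adjusted p = 0.000656, edgeR 0.492). The higher values of Nkx2-3 and Six2 were those of D8 GLI1 OE library 18 and D12 GLI1 OE library 20.

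The authors' deposited table calls 11 genes at D8 (5 higher, 6 lower) and that for D12 calls 78 (73 higher, 5 lower), where edgeR here called 0. At D12 the authors' deposited table gives log2 fold changes of 3.12 for the cartilage collagen gene Col2a1, 4.82 for the lung and thyroid factor gene Nkx2-1 and 2.64 for Eya1, a gene of pharyngeal mesoderm. The values here were 2.96 ± 1.32 (edgeR adjusted p = 0.855), 4.85 ± 1.38 (0.585) and 2.58 ± 0.65 (0.492). Of the genes in the authors' deposited table of selected genes, all 11 for D8 and all 71 tested here of the 74 for D12 had the same direction here.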
